A study of Mus musculus with 6 samples.

How the data were processed

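The series profiled microRNAs (miRNAs, short RNAs that lower the output of messenger RNAs) in primary macrophages of C57BL/6 mice. Per the labels' protocols, all treatments were given to the animals: morphine from an implant under the skin, and lipopolysaccharide (LPS, bacterial endotoxin) injected into the peritoneal cavity. The 6 samples formed 6 groups of 1 array each, from 2 genotypes (WT and MORKO) and 3 treatments (control, LPS and LPS+Morphine), read from the sample titles. No group had a replicate.

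Per the labels' protocols, total RNA was ligated to a linker carrying the dye DY547, and reference DNA oligonucleotides matching part of the mammalian miRNAs carried Alexa Fluor 647. Channel 1 was taken as the sample and channel 2 as a common reference that is no sample of any group. Per the file headers, images were quantified with BlueFuse for Microarrays 3.4 (build 5836), the values of spots with the same name were combined by their mean, the normalization and exclusion entries were empty, and 0 of 4704 spots were excluded. Background handling was not given in the sources used here. The deposited intensity columns hold the amplitude of each channel, per the file headers. The deposited log2 columns hold the log2 ratio of channel 1 over channel 2, without normalization per the file headers. The deposited probability columns hold a fraction between 0 and 1, the probability that a channel is on. The deposited SD column holds the spread of the log2 ratio between the spots of 1 name. There were on average 4.1 spots per name, and values of single spots were not analysed here. Per the file headers all 6 arrays were quantified on the same day, so this day separates no groups, and slides were not examined.

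The authors' value table of the whole series was compared with the scanner values. Each of its columns equalled the channel 1 intensity divided by 1 factor per array, between 188.2 and 339.1, with a coefficient of variation of at most 0.04%. The authors deposited it as a linear ratio of the sample channel to that factor, without the reference channel. Its medians were 0.98, 1.25, 1.19, 0.88, 1.35 and 1.80 for WT control, WT LPS, WT LPS+Morphine, MORKO control, MORKO LPS and MORKO LPS+Morphine. Scale and direction follow from this match, and how the factor was chosen stays unknown.

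Of 1146 names, 374 carried a mouse miRNA name and entered the comparisons. The other 772 and 1 entry with an empty name were left out. Some probes with other species' names are cited beside their mouse namesakes, and their own detection was not checked. A probe counted as detected where the deposited probability of channel 1 was at least 0.5, a threshold chosen once the columns were known. By this call 65 mouse probes were detected on all 6 arrays, 114 on at least 2 and 127 on at least 1. The log2 ratios of each array were centred on their median over the 65 probes. No loess was applied, a choice made in advance on the premise of a nearly constant reference. The premise did not hold, since the reference intensity of miR-16 lay between 348.4 and 1693.9 on the 6 arrays, and loess is among the alternatives. No background was subtracted, because the files used hold no background columns. The log2 sample channel, centred on its 75th percentile over the same 65 probes, was set beside every ratio. Of the 65 probes, the reference channel was on (probability at least 0.5) on all 6 arrays for 17 and on no array for 35, so many ratios divide by a reference signal that was not on.

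Differences between 2 arrays were computed for mouse probes detected on at least 1 of them and counted at 2-fold, which is 1 on the log2 scale. Their error is the combined between-spot SD, the root of the summed squares of the SD on each array, and covers technical spread alone. With 1 array per group these differences have no test and no p-value. For a probe detected on 1 side, a bound was computed from the sample channel: the brighter array against the higher of the lowest detected mouse signal and the probe's own signal on the other array. It leaves out the between-spot error. Where the own signal was the higher, it equals the observed sample channel difference and is no minimum. Beyond the fixed plan, how many 2-fold differences spot noise alone gives was simulated from the combined SD with 4 spots per probe, and differences were correlated across the 65 probes.

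An additive model of genotype and treatment (4 coefficients, 2 residual degrees of freedom) was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The 114 probes detected on at least 2 arrays were tested, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. The fit takes the interaction of genotype and treatment as error. It was tested on simulated data for LPS minus control over 114 probes: 11.8%, 67.2% and 90.2% of probes changed by 1, 2 and 3 on the log2 scale were recovered, with 0.8 false calls per run. In the real fit miR-503 was not called at 1.94 for LPS+Morphine minus LPS (SE 0.52, limma adjusted p 0.784). The recovered shares are therefore not taken as the power of the real fit, and a lack of calls excludes no change. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

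The comparisons, the lists, the rule for named miRNAs and most alternatives were fixed before the data were examined. The rule named miR-146a and miR-155, which the series title mentions, in every comparison. It also named, in each comparison of 2 arrays, up to 10 increases and 10 decreases of at least 2-fold with the same sign in the sample channel, up to 4 detected members of each list with the largest differences, and the 5 smallest adjusted p of each additive fit. Its further condition, the same sign in every pair of spots, was not applied, since single spots were not used. The 18 lists were NF-kB and LPS induced, LPS or tolerance lowered, opioid linked, macrophage and myeloid abundant, let-7 family, miR-17-92 and paralog clusters, miR-23-27-24 clusters, miR-29 and miR-30 families, p53 linked, Dlk1-Dio3 locus, and markers of lymphocytes, erythroid cells, endothelium, fibroblasts and smooth muscle, epithelium, striated muscle, liver and neurons. Of their 140 different names, 132 matched a mouse probe. Older array names were matched to present names by a table written after the probe names were seen; the probe named mouse miR-146 also carries the human name miR-146a and is called miR-146a here. List medians are given with their percentile among 10000 random lists of the same size, matched on intensity in 5 bins, for lists with at least 3 detected members, as a description of these arrays. The random lists were not matched on sequence similarity between members. Whether similar probes of a family or of paralog clusters share signal was not examined, so their percentiles may overstate how unusual they are.

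The alternatives were centring on all mouse probes, loess within array (span 0.3), the sample channel alone scaled by its 75th percentile or by quantiles, the authors' value table, no filter on dim probes, probes detected on all 6 arrays, an intensity trend in eBayes and leaving out each array. A detection probability of 0.9, a limit to probes whose reference channel was on, and the comparison of LPS+Morphine with control were chosen after seeing the data. Conversion to genome positions was left out, because no genome build was named in the sources used here.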

Results

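The mouse macrophage arrays measured miRNAs in 6 samples: untreated control, LPS, and LPS with morphine, each in WT mice and in the mice labelled MORKO. MORKO is read here as a knockout of the mu-opioid receptor, the main target of morphine, although the labels do not spell the abbreviation out. The receptor's messenger RNA is not measured by a miRNA array, so the genotype labels could not be checked. In the order WT control, WT LPS, WT LPS+Morphine, MORKO control, MORKO LPS and MORKO LPS+Morphine, 92, 82, 104, 107, 85 and 80 of 374 mouse probes were detected. The signal over background of the sample channel was 7.79, 7.56, 8.52, 10.41, 10.2 and 9.76 in the same order. The median between-spot SD of the log2 ratio lay between 0.66 and 0.79. With 1 array per group, every difference between groups below compares 2 arrays, and their number limits the precision. Values are differences of centred log2 ratios, followed where stated by the difference in the sample channel. For a probe detected on 1 of 2 arrays the ratio difference is no measured fold. The bound printed beside some of them as "at least" comes from the sample channel without its between-spot error.

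The first comparison asked which miRNAs differed with LPS in WT macrophages. miR-155, which activated macrophages induce through NF-kB, was higher with LPS in the sample channel (1.43) but by 0.21 as a ratio, with a combined between-spot SD of 1.74. Its intensity was 542.6 on the control array and 1414 on the LPS array, and the probe with the human name of miR-155 differed by 0.98 in the sample channel. miR-146a, an NF-kB induced inhibitor of signalling from Toll-like receptors, differed by -0.33 (SD 0.43) and by -0.01 in the sample channel. Its sign turned positive with centring on all mouse probes, loess, quantiles and the authors' value table. The let-7 family, miRNAs that restrain growth genes, was higher as a group: 7 of its 8 detected members lay above 0, with a median of 0.64 at the 99.6th percentile of random lists, positive under all 6 scalings. These members have similar sequences, so their probes are not taken as separate readings. The largest were let-7e (1.09, SD 0.19), let-7g (0.89), let-7f (0.78) and let-7d (0.65). Of the let-7 probes with other species' names, whose detection was not checked, human let-7a was at 0.69, zebrafish let-7g at 0.39, zebrafish let-7i at 0.82, chicken let-7k at 0.20, zebrafish let-7d at 0.02 and human let-7f at -2.47.

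On the WT LPS array miR-142-3p, a miRNA of blood cells, differed from control by -1.45 (SD 0.24; sample channel -0.94), miR-142-5p by -1.13, and miR-342 by -1.99 (SD 0.80; sample channel -1.83). miR-761 differed by -2.10 (SD 0.23; sample channel -1.36). The macrophage and myeloid list had a median of -0.51 (18.2nd percentile; 3 of 10 members at least 2-fold lower), which turned positive with loess and the authors' value table. The list lowered by LPS or in tolerance had a median of -0.68 (15.1st percentile), and 0.13 with the authors' value table. Its members included miR-27b (-0.96, but 0.02 in the sample channel) and miR-98 (-0.41). The opioid linked list, which shares most let-7 members, had a median of 0.64 (99.4th percentile), with miR-23b as the exception at -1.59. The NF-kB and LPS induced list had a median of 0.40 (91.1st percentile), with miR-21 at 0.59. Medians of the Dlk1-Dio3 locus and the miR-17-92 clusters were 0.62 (90.1st percentile) and -0.06 (70.4th percentile; positive under the other 5 scalings). The miR-29 and miR-30 families had a median of -0.46 (38.8th percentile), positive with quantiles and the authors' value table. Lists with fewer than 3 detected members were given no percentile: the medians were -1.27 for miR-23b and miR-27b and -0.07 for the erythroid miR-451 and miR-144, and the fibroblast miR-214 and the muscle miR-206 were at -0.39 and 0.17.

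Of 104 probes, 9 were at least 2-fold higher and 22 at least 2-fold lower. Among probes detected on both arrays these were 2 and 10. Over all 104 probes, 2 and 6 passed 2-fold in the sample channel as well. Spot noise alone gave about 3.5 higher and 3.4 lower if each value is a mean of 4 spots, and 10 and 9.9 with the spread of a single spot. Besides let-7e, miR-709 was detected on both arrays and higher with LPS (1.01, SD 0.25; sample channel 1.20). Probes detected on the LPS array alone were miR-345 (2.09, at least 1.40-fold), miR-708 (2.06, at least 1.17-fold), miR-669a (1.69, at least 1.39-fold), miR-670 (1.30, at least 1.54-fold), miR-676* (1.21, at least 1.24-fold) and miR-539 (1.20, at least 1.35-fold). miR-455-3p (1.96, SD 4.66) was detected on the control array alone, so no fold is given. On the control array alone, miR-764-3p (-2.96, at least 1.28-fold), miR-452 (-2.94, at least 2.19-fold), miR-28 (-2.64, at least 1.32-fold), miR-216b (-2.49, at least 1.14-fold), miR-17-3p (-2.19, at least 1.57-fold), miR-9* (-2.16, at least 1.02-fold), miR-335 (-2.10, at least 1.33-fold) and miR-542-3p (-1.97, at least 1.14-fold) were detected. The split of higher against lower was 24 to 16 with centring on all mouse probes, 19 to 24 with loess, 7 to 7 in the sample channel, 6 to 8 with quantiles and 12 to 3 in the authors' value table. These scalings moved the median of all probes by 0.29 to 0.61.

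**Figure D1:**
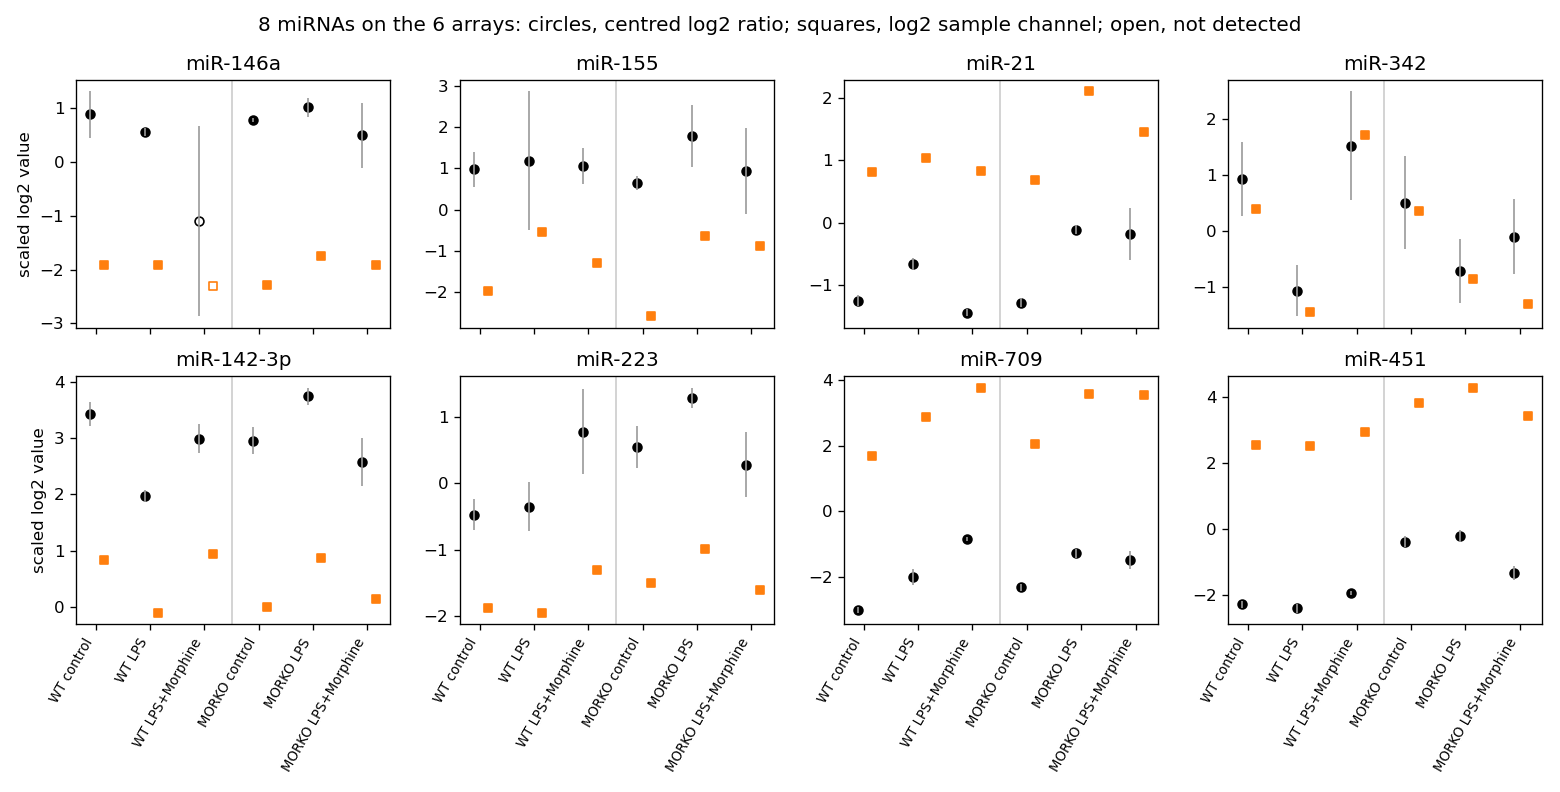
Scaled log2 values (vertical axes) of 8 miRNAs on each of the 6 arrays (horizontal axes): circles are centred log2 ratios with the between-spot SD as bars, squares the log2 sample channel, and open symbols mark arrays without detection. miR-146a is open on the WT LPS+Morphine array, with a ratio of -1.10 and a between-spot SD of 1.77, and miR-451 lies higher on each MORKO array than on the WT array of the same treatment, although with quantiles, which compare ranks, the control arrays differ by 0.0.

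The second comparison asked what morphine added to LPS in WT macrophages, the setting of the series title. miR-146a was lower by ratio on the WT LPS+Morphine array (-1.64), within a combined between-spot SD of 1.78. The probability of its sample channel was 0.24 there, so it was not detected. The WT LPS array was 1.30-fold brighter in the sample channel, a value without between-spot error. The sample channel difference of miR-146a was -0.37, and the 6 scalings ranged from -2.12 to -0.37. The reference intensity of this probe was 249.1 on that array and 73.1 on the WT LPS array. miR-155 differed by -0.13 (SD 1.75; sample channel -0.75). The NF-kB and LPS induced list was lower under all 6 scalings, with a median of -0.81 at the 0.7th percentile: all 4 detected members lay below 0, including let-7e (-0.84) and miR-21 (-0.79). These were 4 of 13 matched probes, and miR-146a among them was detected on the WT LPS array alone. In the sample channel the median was -0.29, with let-7e at -0.185 and miR-21 at -0.211.

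miR-342, miR-761 and miR-142-3p, lower on the WT LPS array, were higher again with morphine. miR-342 differed by 2.59 (SD 1.08; sample channel 3.16), miR-761 by 1.76 (sample channel 1.49), and miR-142-3p by 1.02 (SD 0.27; sample channel 1.04). miR-223, a myeloid miRNA that differed by 0.12 with LPS, differed by 1.13 (SD 0.74) with morphine. Both comparisons use the WT LPS array, and across the 65 probes detected on all arrays, which are not independent replicates, the ratio differences correlated at r = -0.67 (Spearman -0.63) with a covariance of -0.486. Simulated arrays of independent noise gave r = -0.50 and a covariance of -0.287. This r follows from the shared array alone. The noise took each probe's variance over all 6 arrays, differences between the groups included. The simulation therefore sets no level for arrays without effects, and no conclusion is drawn from it. The list lowered by LPS or in tolerance had a median of 0.95 (88.7th percentile), positive under all 6 scalings, as was that of the Dlk1-Dio3 locus (1.08, 80.1st percentile), with miR-329 at 2.502 (at least 1.79-fold) and miR-376b at 1.79. The miR-17-92 clusters, linked to cell growth, had a median of -0.50 (1.1st percentile), negative under all 6 scalings. Members were miR-18 at -1.31, although at 0.38 in the sample channel, and miR-106a at -1.002. The let-7 family had a median of -0.51 (1.3rd percentile), near 0 in the sample channel (-0.02), with let-7g at -1.40 (sample channel 0.08). The opioid linked list (-0.48, 4.3rd percentile) turned positive in the sample channel (0.19). The macrophage and myeloid list (0.31, 59.0th percentile) turned negative with loess, quantiles and the authors' value table, and the miR-29 and miR-30 families (0.36, 57.5th percentile) with loess and that table. Single markers of other cells were miR-214 (1.80) and miR-143 (0.38) of fibroblasts, miR-203 (2.78) and miR-200a (-1.38) of epithelium, and miR-206 (-1.498) of striated muscle. For miR-200a the sample channel went the other way (0.88). It was detected on the LPS+Morphine array alone, at least 1.84-fold brighter there, so no direction is stated. The erythroid miR-144 and miR-451 differed by 0.47 and 0.45, and miR-23b, alone detected of its clusters, by 0.64.

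Of 115 probes, 34 were at least 2-fold higher and 10 lower, 15 and 5 among those detected on both arrays, and, over all 115, 21 and 0 in the sample channel as well. Spot noise alone gave about 3.8 and 3.7, or 12.0 and 11.9 with the single-spot spread. Further named probes were miR-320 (2.33, SD 0.58), and, detected with morphine alone, miR-452 (3.53, at least 3.79-fold), miR-185 (3.47, at least 2.22-fold), miR-665 (2.47, at least 1.64-fold), miR-764-3p (2.43, at least 2.15-fold), miR-28 (2.36, at least 1.54-fold) and miR-542-3p (2.33, at least 1.44-fold). miR-16 differed by -2.25 as a ratio but by -0.40 in the sample channel. miR-345 (-3.07, at least 1.22-fold), miR-374-5p (-1.60, at least 1.36-fold) and miR-350 (-1.41, at least 1.02-fold) were detected on the LPS array alone. The split was 25 to 22 with loess, 27 to 1 in the sample channel and 10 to 9 in the authors' value table, and scalings shifted the median of all probes by -0.51 to 0.13. Set against control instead, a comparison added after seeing the data, the WT LPS+Morphine array had 17 probes higher and 12 lower of 113, with miR-146a at -1.98 (sample channel -0.38).

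The same LPS comparison in MORKO macrophages showed miR-155 higher by 1.14 (SD 0.77; sample channel 1.97), positive under all 6 scalings, with the probe of the human name at 1.66 in the sample channel. miR-21 was higher by 1.17 (SD 0.10; sample channel 1.42), miR-691 by 1.21 (SD 0.08; sample channel 1.26) and miR-709 by 1.04 (sample channel 1.52). miR-146a differed by 0.24 (SD 0.18; sample channel 0.55), and turned negative with centring on all mouse probes and with loess. miR-342 was lower here too (-1.22, SD 1.01; sample channel -1.23), under all 6 scalings. Across the 65 probes the LPS differences of the 2 genotypes, which share no array, correlated at r = 0.25 as ratios (Spearman 0.24) and 0.62 in the sample channel (Spearman 0.37).

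By list, the NF-kB and LPS induced list had a median of 0.69 (93.1st percentile) and the miR-23-27-24 clusters of 0.85 (96.6th percentile), both positive under all 6 scalings, as was the list lowered by LPS or in tolerance (0.65, 96.5th percentile), whose 6 detected members all lay above 0, including miR-27b (0.85), miR-142-3p (0.79), miR-223 (0.74) and miR-142-5p (0.55). The miR-17-92 clusters had a median of 0.55 (93.6th percentile), and -0.01 with centring on all mouse probes. The let-7 family (0.23, 35.7th percentile) and the opioid linked list (0.25, 57.3rd percentile) turned negative with that centring, loess and quantiles, and the macrophage and myeloid list (0.24, 51.4th percentile) with that centring. Medians were -0.02 (30.0th percentile) for the miR-29 and miR-30 families, positive under 4 other scalings, -0.28 (22.3rd percentile) for the Dlk1-Dio3 locus, positive in the sample channel and the authors' value table, and 0.17 (43.1st percentile) for erythroid miRNAs, not above 0 with centring on all mouse probes, loess and quantiles. The fibroblast miR-214 and miR-143 were at -0.94 and 0.44, miR-200a of epithelium at 0.00 after rounding and miR-206 of striated muscle at -1.03.

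Of 114 probes, 12 were at least 2-fold higher and 12 lower, 8 and 4 among those detected on both arrays, and, over all 114, 5 and 4 in the sample channel as well, against about 2.9 and 2.9 from spot noise, or 9.3 and 9.3 with the single-spot spread. Other named increases were miR-382 (1.79, at least 2.67-fold), miR-23b (1.70), miR-20a (1.32, SD 2.13), miR-676 (1.26) and miR-107 (1.15), and miR-201 (1.27) and miR-19a (1.05), which turned negative with quantiles; miR-201, miR-676 and miR-19a were detected on the control array alone, so no fold is given. Lower ratios with LPS were those of miR-695 (-1.07), miR-674* (-2.31, at least 1.87-fold) and miR-335 (-1.08, at least 1.02-fold, above 0 in the authors' value table). miR-546 (-3.27), miR-376b (-1.34) and miR-675-5p (-1.24, sample channel -0.17) were detected on the control array alone, and no fold can be given for them. The split was 2 to 22 with centring on all mouse probes, 5 to 14 with loess, 8 to 4 in the sample channel, 1 to 5 with quantiles and 9 to 3 in the authors' value table, with shifts of the median of all probes from -0.56 to 0.38.

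**Figure D2:**
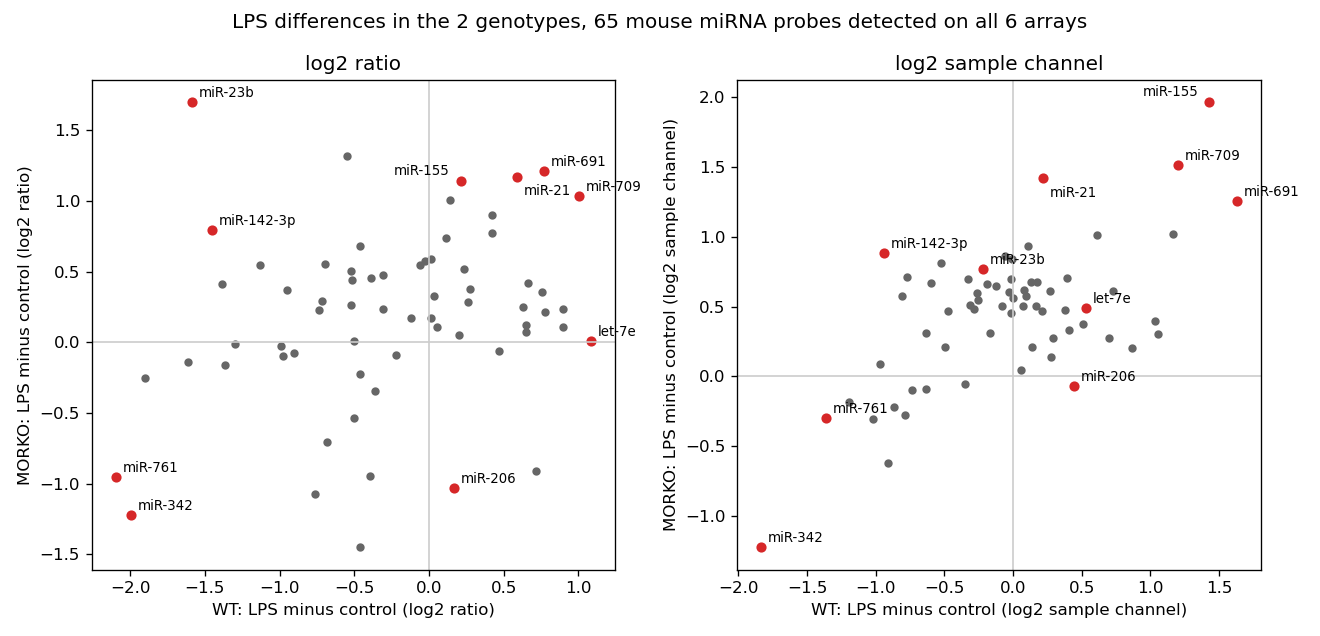
LPS minus control in MORKO (vertical axes) against WT (horizontal axes), as log2 ratios (left) and in the log2 sample channel (right); each point is 1 of 65 mouse probes detected on all 6 arrays, and red points are named. miR-342 lies below 0 on both axes of both panels, and miR-155 reaches 1.43 in WT and 1.97 in MORKO in the sample channel.

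With morphine on top of LPS in MORKO macrophages, fewer probes differed by 2-fold. miR-142-3p (-1.18, SD 0.46; sample channel -0.73), miR-223 (-1.01, SD 0.51; sample channel -0.61) and miR-320 (-1.07, SD 0.31; sample channel -0.59) were lower, under all 6 scalings. The erythroid miR-144 and miR-451, made in developing red blood cells, were lower as well (-1.58 and -1.13), also under all 6 scalings. miR-146a differed by -0.52 (SD 0.63; sample channel -0.17) and turned positive with quantiles and the authors' value table. miR-155 differed by -0.86 (SD 1.29; sample channel -0.25), and by 0.20 in the authors' value table.

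The list lowered by LPS or in tolerance had a median of -0.74 (2.4th percentile), and 0.12 in the authors' value table, with miR-27b at -1.36 and above 0 in that table. The miR-17-92 clusters (0.24, 98.1st percentile) turned negative with centring on all mouse probes and in the sample channel, and the miR-29 and miR-30 families (0.35, 97.0th percentile), with miR-30c at 1.32, in the sample channel. The NF-kB and LPS induced list (-0.29, 46.1st percentile) and the macrophage and myeloid list (-0.32, 41.6th percentile) turned positive with loess and the authors' value table. The opioid linked list (-0.30, 40.2nd percentile) and the let-7 family (-0.29, 40.4th percentile) turned positive with loess, quantiles and that table, the let-7 family also in the sample channel. The Dlk1-Dio3 locus had a median of -0.63 (27.1st percentile), and 0.07 with loess, with miR-382 at -1.49. Lists with fewer than 3 detected members were miR-27b and miR-23b (median -0.57), miR-214 and miR-143 (-0.17), miR-200a (0.19) and miR-206 (0.12).

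Of 90 probes, 4 were at least 2-fold higher and 10 lower, 2 and 8 among those detected on both arrays, and, over all 90, 0 and 2 in the sample channel as well, against about 1.7 and 1.7 from spot noise, or 6.3 and 6.2 with the single-spot spread. The named increases were miR-669a (2.08, at least 1.04-fold), miR-669c (1.54, SD 3.74) and miR-30c (at least 1.14-fold), and further decreases were miR-674 (-1.03), miR-18 (-1.14), positive in the authors' value table, and miR-191 (-1.02), at 0.00 with quantiles and positive in that table. The split was 3 to 19 with centring on all mouse probes, 10 to 6 with loess, 0 to 2 in the sample channel, and 0 to 0 with quantiles and in the authors' value table, with shifts of the median of all probes from -0.31 to 0.55. Set against MORKO control, a comparison added after seeing the data, 5 of 107 probes were higher and 13 lower.

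Between the untreated genotypes, the ratios of the erythroid miRNAs all lay above 0, and miR-451 (1.90, SD 0.19, sample channel 1.30) was higher in MORKO. miR-144 (1.65, SD 1.95, sample channel 0.307) lay within its combined between-spot SD. miR-486 (1.81, sample channel 0.735) was detected on the MORKO array alone, so its ratio is no measured fold. The erythroid list median was 1.81, the value of miR-486, at the 99.5th percentile and positive under all 6 scalings. For miR-451 the quantile difference was 0.00, which reflects its rank among the probes and not its level. Its intensity was 40845.7 on the MORKO control array and 12374.4 on the WT control array. The let-7 family was higher under all 6 scalings (median 0.49, 99.3rd percentile, 8 of 8 members above 0), with let-7d at 0.94 and let-7e at 0.90. Probes with other species' names were above 0 for human let-7a (0.68), zebrafish let-7g (0.53), zebrafish let-7i (0.19) and chicken let-7k (0.47), and below 0 for zebrafish let-7d (-0.17) and human let-7f (-0.51). miR-223 was higher (1.01, SD 0.39), while miR-142-5p (-0.99) and miR-142-3p (-0.47) were lower. miR-146a differed by -0.11 (SD 0.43; sample channel -0.38), turning positive with centring on all mouse probes, loess and quantiles, and miR-155 by -0.33 (SD 0.46; sample channel -0.63), turning positive with that centring.

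The other medians between untreated genotypes were 0.31 for the opioid linked list (87.2nd percentile, negative with loess) and 0.49 for the Dlk1-Dio3 locus (80.7th percentile, negative in the sample channel). Of that locus, miR-379 was at 1.95 (SD 3.21), but at -0.21 in the sample channel. They were -0.38 for the miR-23-27-24 clusters (14.6th percentile, positive with centring on all mouse probes and loess) and -0.14 for the miR-17-92 clusters (33.2nd percentile, positive with that centring). Medians near 0, which lost their sign under at least 3 scalings, were those of the NF-kB and LPS induced (-0.07, 46.9th percentile), LPS or tolerance lowered (-0.11, 43.4th percentile), macrophage and myeloid (-0.14, 19.5th percentile) and miR-29 and miR-30 (-0.02, 52.0th percentile) lists. miR-214, miR-200a and miR-206 were at 0.82, 1.44 and -1.04, with miR-214 at -0.44 in the sample channel. The p53 linked, lymphocyte, endothelial, liver and neuronal lists had 0 detected members in every comparison.

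Of 115 probes, 15 were at least 2-fold higher in MORKO control and 8 lower, 5 and 5 among those detected on both arrays, and, over all 115, 2 and 3 in the sample channel as well, against about 2.8 and 2.7 from spot noise, or 9.0 and 8.8 with the single-spot spread. Other named increases were miR-455-3p (2.19, SD 4.45), miR-669a (1.92), miR-670 (1.5, at least 1.03-fold), miR-674* (1.35, at least 2.02-fold), miR-30c (1.27) and miR-676* (1.07). miR-669a, miR-30c, miR-676* and the erythroid miR-486 were detected on the MORKO array alone and allow no fold. Named decreases were miR-9* (-3.20, at least 1.97-fold), miR-17-3p (-2.08), miR-23b (-1.98), miR-26b (-1.502, at least 2.40-fold), miR-20a (-1.34) and miR-19b (-1.13, SD 0.24; sample channel -1.10). The split was 28 to 4 with centring on all mouse probes and 4 to 6 in the sample channel, with shifts of the median of all probes from -0.27 to 0.47.

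Whether the difference with morphine depended on genotype was asked as WT minus MORKO of the morphine differences. miR-146a was at -1.13 (SD 1.89; sample channel -0.20), negative under all 6 scalings, and miR-155 at 0.73 (SD 2.17; sample channel -0.51), negative under 4 scalings. The myeloid miR-142-3p (2.20) and miR-223 (2.14) were higher in WT than in MORKO by this measure. Lists with the same sign under all 6 scalings were NF-kB and LPS induced (-0.89, 1.2nd percentile; sample channel -0.001), the miR-17-92 clusters (-0.47, 3.8th percentile) and the Dlk1-Dio3 locus (1.31, 84.9th percentile). The list lowered by LPS or in tolerance had a median of 1.06 (81.3rd percentile), and turned negative with loess and the authors' value table. The opioid linked (0.08, 31.4th percentile) and macrophage and myeloid (0.75, 69.7th percentile) lists turned negative with loess, quantiles and that table. The let-7 family (-0.27, 6.7th percentile) and the miR-29 and miR-30 families (-0.21, 18.0th percentile) turned positive in the sample channel. Lists with fewer than 3 detected members had medians of 1.82 (miR-144 and miR-451), 0.01 (miR-23b and miR-27b), 1.26 (miR-214 and miR-143) and 0.97 (miR-203 and miR-200a), and miR-206 was at -1.62. Of 121 probes, 43 were at least 2-fold higher and 17 lower (31 and 1 in the sample channel as well). The split was 47 to 10 with centring on all mouse probes, 29 to 32 with loess, 40 to 3 in the sample channel and 8 to 22 in the authors' value table, with shifts of the median of all probes from -0.72 to 0.22. Across the 65 probes the morphine differences of the genotypes correlated at r = -0.18 as ratios (Spearman -0.22) and -0.25 in the sample channel (Spearman -0.29).

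For LPS, WT minus MORKO of the differences contains both LPS arrays, as does the morphine measure with opposite signs, so these measures are not independent. It was -0.57 for miR-146a (SD 0.47, sample channel -0.56), turning positive with centring on all mouse probes, loess and quantiles. For miR-155 it was -0.93 (SD 1.91, sample channel -0.53), turning positive with that centring and quantiles. miR-142-3p (-2.25), miR-27b (-1.81) and miR-142-5p (-1.68) led the list lowered by LPS or in tolerance, with a median of -1.30 at the 1.9th percentile, negative under all 6 scalings. The miR-23-27-24 clusters were negative under all 6 scalings too (-1.82, 2.7th percentile), while the let-7 family (0.47, 99.6th percentile) and the opioid linked list (0.38, 96.6th percentile) were positive under all 6. The NF-kB and LPS induced list (-0.58, 48.7th percentile) and the Dlk1-Dio3 locus (-0.32, 51.1st percentile) turned positive with centring on all mouse probes, loess and quantiles. The macrophage and myeloid list (-0.62, 23.8th percentile) turned positive with that centring, the miR-17-92 clusters (-0.86, 23.6th percentile) with that centring and quantiles, and the miR-29 and miR-30 families (-0.23, 64.9th percentile) and erythroid miRNAs (-0.30, 65.5th percentile) with that centring and loess. The fibroblast pair miR-143 and miR-214 had a median of -0.37, and miR-200a and miR-206 were at 1.49 and 1.19. Of 122 probes, 17 were at least 2-fold higher and 31 lower (3 and 11 in the sample channel as well). The split was 39 to 10 with centring on all mouse probes, 33 to 17 with loess, 4 to 17 in the sample channel and 10 to 4 with quantiles, with shifts of the median of all probes from -0.04 to 0.999.

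The additive limma fit, the only test here, called 0 of 114 probes for LPS minus control, LPS+Morphine minus LPS and MORKO minus WT, with 1, 4 and 5 probes at an unadjusted p under 0.05. The smallest Benjamini-Hochberg adjusted p were 0.68, 0.784 and 0.782. For LPS the smallest p belonged to miR-465 (-1.14), miR-542-3p (-1.29), miR-342 (-1.61), miR-761 (-1.53) and miR-96 (0.76). For LPS+Morphine they belonged to miR-675-5p (1.76), miR-542-3p (1.86), miR-503 (1.94), miR-18 (-1.23) and miR-342 (1.60), and for MORKO to miR-411 (0.99), miR-451 (1.57), miR-210 (-0.82), miR-206 (-1.30) and miR-201 (1.02). In the sample channel the same probes, in the same order, were at -0.09, -1.96, -1.53, -0.83 and 0.68 for LPS. They were at 0.64, 0.36, 0.85, -0.005 and 1.36 for LPS+Morphine, and at 0.62, 1.19, -0.40, -0.85 and 0.12 for MORKO. miR-146a was estimated at -0.05 (SE 0.53) for LPS and -1.08 (SE 0.53, limma adjusted p 0.93) for LPS+Morphine, and miR-155 at 0.68 (SE 0.39) and -0.49 (SE 0.39).

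In the sample channel at its 75th percentile the same limma fit called 3 probes for LPS: miR-155 rose by 1.70 (SE 0.46, adjusted p 0.0157), miR-342 fell by 1.53 (adjusted p 0.0388) and miR-542-3p fell by 1.96 (adjusted p 0.00325). The last rested on the MORKO control array, where its intensity was 6293.9 with a detection probability of 0.49, against 349.1 to 473.5 on the others. For LPS+Morphine 1 probe was called, miR-19a, at -1.70 (adjusted p 0.031), but the ratio fit gave 0.37 and both LPS+Morphine arrays were below detection (0.32 and 0.25), so no direction is stated. All 114 probes shared the SE of 0.46, a fully pooled spread. With quantile scaling of the same channel limma called 0 probes for LPS and 0 for LPS+Morphine (smallest adjusted p 0.442 and 0.101), with 8 and 5 at an unadjusted p under 0.05. In the authors' value table miR-691 rose by 1.64 and miR-709 by 1.55 with LPS (limma adjusted p 0.0496 for both), and miR-451 was higher by 1.60 in MORKO (adjusted p 0.0174).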

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

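Apart from the additive limma fit, which was fixed in advance, all tests in this part were chosen only after the results were seen. So were the size criteria used to pick the results below and the explanations weighed.

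Some miRNAs differed with morphine in opposite directions in the 2 genotypes, by at least 0.5 each way as centred log2 ratios and with the same signs, of any size, in the sample channel. These differences were not tested. As WT minus MORKO they were 2.44 for miR-191, 2.14 for miR-223, 1.23 for miR-29a, 3.396 for miR-320, -1.51 for miR-106a, 2.20 for miR-142-3p, 1.66 for miR-491, 1.39 for miR-710, 1.89 for miR-711 and 2.27 for miR-721. Over all probes this measure had a median of 0.459, from 0.33 in WT and -0.279 in MORKO. In the sample channel some were near 0: miR-191 differed by 0.05 in WT and -0.16 in MORKO. There miR-29a differed by 0.337 in WT and -0.031 in MORKO, and miR-106a by -0.602 and 0.042. Both genotypes kept their direction under all 6 scalings for miR-223, miR-320, miR-106a and miR-142-3p, under 5 for miR-491 and miR-710, under 4 for miR-191, miR-711 and miR-721, and under 3 for miR-29a. The centred ratio and the sample channel are among the 6 and agree by the way these miRNAs were picked. Both directions were swapped under 1 scaling for miR-191 and under 2 for miR-29a. For LPS the same measure was -1.68 for miR-142-5p (both directions kept under 5 scalings), -1.25 for miR-19b (under 3), -3.29 for miR-23b (under 5) and -2.25 for miR-142-3p (under all 6), also untested. The measures for LPS and morphine both contain the WT LPS and MORKO LPS arrays, with opposite signs, so they are not independent. For miR-142-3p, MORKO LPS minus WT LPS alone was 1.775. The probe with the human name of miR-142-3p differed in the sample channel by -1.02 with LPS and 1.34 with morphine in WT, and by 0.66 and -0.73 in MORKO. It was read on the same arrays, and within each genotype its LPS and morphine differences share the LPS array, so opposite signs can come from that array alone.

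Of 15 probes whose names mark them as added, 7 were detected on at least 1 array and 2 on all 6. The small nucleolar RNA probe 5SN1, which carries a human name, was brighter on all 4 treated arrays than on both control arrays. The gap was at least 0.882 in the log2 sample channel. For E1, also human-named and detected on 5 arrays, it was at least 0.483, but E1 was below detection on WT control (probability 0.41). The other 5 (U6, E3, U46, U49 and a miR-21 probe) did not show this order. How many of 15 probes would show it by chance was not examined. The intensity of 5SN1 was 3584.5, 6385.1, 7690.6, 4091.2, 6529.2 and 7702.4 from WT control to MORKO LPS+Morphine.

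The lower miR-146a ratio on the WT LPS+Morphine array is the pattern closest to the series title. Noise of the reference channel may account for much of it, since the sample channel differed by -0.374 and the ratio by -1.64. A deviation of this 1 probe is open as well, since the zebrafish-named miR-146a probe differed by 0.477 in the sample channel, although by -0.486 as a ratio. Detection of the zebrafish-named probe was not checked. Neither excludes a lower level with morphine, because the probe was below detection there and no replicate exists. The biological explanation, an effect of morphine on miR-146a, stays open: the additive limma fit over both genotypes did not call it (-1.08, SE 0.53, adjusted p 0.93), and in WT alone it was not tested.

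Most ratios of the erythroid miRNAs were higher on MORKO than on WT arrays, with miR-451, an abundant red blood cell miRNA, at intensities of 24647.1 to 40845.7 against 11822.8 to 12734.5. In all, 8 of 9 differences lay above 0, the exception being miR-486 with LPS+Morphine, but this count restates the pattern and decides nothing. miR-486 was below detection on both LPS+Morphine arrays and also on both LPS arrays, where its 1.208 counts among the 8, so the pattern rests mainly on miR-451 and miR-144. On the control arrays miR-486 was detected in MORKO alone, and miR-144 lay within its combined between-spot SD (1.65, SD 1.95). The scaling of the arrays was not excluded, since the lowest median over the scalings, with quantiles, was 0.285 against 1.368 in the centred ratios. Red blood cells in the macrophage harvest cannot be told apart from a difference between the genotypes in macrophages themselves.

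The 22 miRNAs at least 2-fold lower on the WT LPS array may reflect a deviation of that array alone, or an LPS effect in WT. On the MORKO arrays their LPS differences had a median of -0.014, with quartiles of -0.518 and 0.524 and 12 below 0, so the members went both ways and the explanations cannot be told apart. In the sample channel that median was 0.089, and the MORKO LPS differences of all probes had a median of 0.148. The MORKO summaries of the 22 include members such as miR-28 and miR-465, detected on neither MORKO array. Others, such as miR-335, were detected on the MORKO control array alone. For all of these the MORKO difference is no measured fold. Members detected on both MORKO arrays also went both ways, such as miR-342 (-1.22) and miR-23b (1.70). Without the WT LPS array, LPS+Morphine minus control in WT had a median of -0.386 over the 22, which shares the WT control array. The WT LPS array had 81.55% of spots in the lowest confidence class, against 73.38% to 79.36% on the others. Its signal over background was the lowest in both channels (sample 7.56, reference 6.59). Whether scan quality bears on the 22 was not tested. The verdict rules for this test and for the red blood cells were made stricter after their results were seen.

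For MORKO minus WT in the additive limma fit, the real split of the 6 arrays gave 0 calls and the highest of the other splits gave 0. With no calls in any split this comparison shows nothing. Probes at an unadjusted p under 0.05 numbered 5 in the real split and 3 to 10 in the others, and 10 splits are too few for a share under 0.05.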

How the results depend on the processing

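A detection probability of 0.9 and the limit to probes whose reference channel was on were chosen only after the data were seen. Splits below are counts of probes at least 2-fold higher to at least 2-fold lower, and the cause of each move was not tested, except that the filters change how many probes are counted. WT morphine and MORKO morphine stand for LPS+Morphine minus LPS, WT LPS and MORKO LPS for LPS minus control. Both background alternatives and the median of spots were not run, since background columns and single-spot values were not used here. Leaving out each array or fitting an intensity trend gave 0 limma calls. The signal over background of the sample channel was 7.56 to 10.41, and 80 to 107 of 374 mouse probes were detected per array. Where a probe was below detection on 1 of 2 arrays, at most a bound can be given. Sign changes are named below only where the centred ratio was at least 2-fold, and counted for smaller values of named miRNAs and medians of lists.

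Centring on all mouse probes gave 24 to 16 for WT LPS, 25 to 11 for WT morphine, 2 to 22 for MORKO LPS and 3 to 19 for MORKO morphine. With the same setting the split was 28 to 4 for the untreated genotypes, 47 to 10 for the genotype difference of morphine and 39 to 10 for the genotype difference of LPS. miR-146a moved to 0.105 for WT LPS, -0.324 for MORKO LPS, 0.362 for the untreated genotypes and 0.430 for the genotype difference of LPS. miR-155 moved to 0.146 for the untreated genotypes. Signs turned for 6 smaller miRNA values and 19 smaller list medians.

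Loess within array gave 19 to 24 for WT LPS, 25 to 22 for WT morphine, 5 to 14 for MORKO LPS and 10 to 6 for MORKO morphine. It was 20 to 8 for the untreated genotypes, 29 to 32 for the genotype difference of morphine and 33 to 17 for the genotype difference of LPS. miR-146a moved to -0.288 for MORKO LPS and 0.289 for the genotype difference of LPS. Signs turned for the median of the list LPS or tolerance lowered (-0.702, the genotype difference of morphine), and for 5 smaller miRNA values and 23 smaller list medians.

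The sample channel at its 75th percentile gave 7 to 7 for WT LPS, 27 to 1 for WT morphine, 8 to 4 for MORKO LPS and 0 to 2 for MORKO morphine. It was 4 to 6 for the untreated genotypes, 40 to 3 for the genotype difference of morphine and 4 to 17 for the genotype difference of LPS. miR-146a moved to 0.548 for MORKO LPS. miR-155 moved to 1.965 for MORKO LPS. Signs turned for 1 smaller miRNA value and 10 smaller list medians. limma calls went from 0 to 3 for LPS minus control and 1 for LPS+Morphine minus LPS.

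Quantile scaling gave 6 to 8 for WT LPS, 14 to 4 for WT morphine, 1 to 5 for MORKO LPS and 0 to 0 for MORKO morphine. It was 5 to 3 for the untreated genotypes, 19 to 9 for the genotype difference of morphine and 10 to 4 for the genotype difference of LPS. miR-146a moved to 0.142 for WT LPS, 0.037 for MORKO LPS and 0.105 for the genotype difference of LPS. Signs turned for miR-19a (-0.346, MORKO LPS) and miR-201 (-0.418, MORKO LPS), and for 6 smaller miRNA values and 17 smaller list medians.

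The authors' value table gave 12 to 3 for WT LPS, 10 to 9 for WT morphine, 9 to 3 for MORKO LPS and 0 to 0 for MORKO morphine. It was 6 to 3 for the untreated genotypes, 8 to 22 for the genotype difference of morphine and 6 to 9 for the genotype difference of LPS. miR-146a moved to 0.314 for WT LPS, 0.613 for MORKO LPS and 0.274 for MORKO morphine. miR-155 moved to 2.028 for MORKO LPS and -1.445 for the genotype difference of morphine. Signs turned for miR-335 (0.026, MORKO LPS), miR-18 (0.062, MORKO morphine), miR-191 (0.285, MORKO morphine), miR-27b (0.141, MORKO morphine) and the median of the list LPS or tolerance lowered (-0.123, the genotype difference of morphine), and for 4 smaller miRNA values and 18 smaller list medians. limma calls went from 0 to 2 for LPS minus control and 1 for MORKO minus WT.

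All 374 mouse probes gave 51 to 113 for WT LPS, 127 to 57 for WT morphine, 100 to 51 for MORKO LPS and 70 to 61 for MORKO morphine. It was 56 to 97 for the untreated genotypes, 153 to 68 for the genotype difference of morphine and 67 to 155 for the genotype difference of LPS.

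Probes detected on all 6 arrays gave 2 to 10 for WT LPS, 15 to 5 for WT morphine, 7 to 4 for MORKO LPS and 2 to 8 for MORKO morphine. It was 3 to 4 for the untreated genotypes, 23 to 8 for the genotype difference of morphine and 3 to 15 for the genotype difference of LPS.

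Detection at 0.9 gave 2 to 12 for WT LPS, 18 to 6 for WT morphine, 6 to 5 for MORKO LPS and 2 to 5 for MORKO morphine. It was 8 to 4 for the untreated genotypes, 26 to 11 for the genotype difference of morphine and 9 to 16 for the genotype difference of LPS.

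Probes with the reference on gave 3 to 2 for WT LPS, 10 to 1 for WT morphine, 4 to 3 for MORKO LPS and 0 to 4 for MORKO morphine. It was 3 to 1 for the untreated genotypes, 13 to 2 for the genotype difference of morphine and 3 to 4 for the genotype difference of LPS.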

Other observations

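The correlations in this part were chosen only after the data were seen, and probes are not independent replicates.

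Over the 65 probes detected on all arrays, the MORKO LPS and morphine differences, which share the MORKO LPS array, correlated at r = -0.46 as ratios (Spearman -0.43, covariance -0.173) and -0.11 in the sample channel (Spearman -0.10, covariance -0.017). Simulated arrays of independent noise gave r = -0.50 in both, with covariances of -0.282 and -0.22. That r follows from the shared array alone. The noise took each probe's variance over all arrays, differences between the groups included. The simulated covariances therefore set no level for arrays without effects, and no conclusion is drawn from them. For WT in the sample channel r was -0.70 (Spearman -0.65) and the covariance -0.337. Across all probes of each array, intensities of the sample and reference channels ranked in opposite order, with Spearman correlations between -0.51 and -0.36.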
